A study of Mus musculus with 17 samples.

How the data were processed

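The data were 17 peak lists of ATAC-seq libraries from mouse thymocytes (C57BL/6J, 4.5 to 7 weeks of age, 30000 to 50000 cells per library, thymi of 8 to 10 sex-matched mice pooled), 1 list per library. Replicates are separate pools by the labels, and those of a stage come from different batches. The p-values therefore measure the spread between pools and batches together. The submitters' processing notes name Bowtie2, Picard, SAMtools, Genrich and deepTools 3.5.1 and the build GRCm38/mm10, with no role or order for each. Which parameters and filters were used, and whether cut sites were shifted for the transposase, is not given in the sources used here.

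Each list gives, per the deposited files, a peak's start, end and summit in bp, a display score of up to 1000, a signal, which is the area of the peak and is never below 200, and the −log10 of the p-value at its summit. The score, signal and −log10 p are the authors' own values for each peak and were used here only to rank or filter peaks within a list. The q-value column held no computed value. No peak lay on chromosome Y or the mitochondrial genome, and peaks on unplaced contigs were left out. The read depth of the libraries is not given in the sources used here, so no interval for counting error can be had. Precision is set by the number of libraries, and list length stands in for depth as a limit: after removal of contigs the lists held 67137, 64244 and 32351 peaks for ETP replicates 1 to 3, 72331, 87861 and 85208 for ETP_trans, 73262, 81288 and 91263 for DN2a, 79268, 71695 and 82647 for DN2b, 74696, 80073 and 83316 for DN3, and 71438 and 68990 for DN4. DN4 replicate 1 had wider peaks (median 645 bp) than the other 16 lists (381 to 512 bp).

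Peaks overlapping by at least 1 bp were merged over all lists, and the 112973 merged regions with a peak in at least 2 libraries were kept, leaving out 33038 with a peak in 1 library. A region was assigned to the nearest gene body within 100000 bp (21627 protein-coding genes and 510 antigen receptor segments of the GRCm38.p6 gene table, the build of the lists), ties going to the nearer gene end, which placed 106397 regions (94.2%) at 16936 loci. The plan named the transcription start, but the table gives no strand, so gene bodies, and either gene end for the share at promoters, took its place. Of the listed symbols, 1 of 24 T specification factors, 1 of 20 β-selection genes and 1 of 18 natural killer genes were not in the table. Motif tests were planned for the case that a genome was given and were not run.

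The number of regions with a peak per locus was scaled to the median list length (74696 peaks), 1 was added, and log2 values were fitted with limma 3.58.1 (trend and robust options) in R 4.3.3, with 1 mean per stage over all 17 libraries and no covariate. The 5 contrasts of consecutive stages and the contrast of the mean of DN3 and DN4 against the mean of ETP and ETP_trans were tested over 11003 loci with at least 3 regions, with Benjamini-Hochberg adjustment at a threshold of 0.05. Gene lists (13 by name and 4 by receptor segment symbol) were tested with camera at a preset correlation of 0.01, adjusted over the 17 lists, and again with an estimated correlation. Presence of a peak per region was compared between the 6 early and 5 late libraries with 2-sided Fisher exact tests in Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9. For consecutive stages, regions with a peak in all libraries of one stage and none of the other were counted, since 3 against 3 libraries cannot reach 0.05 per region. Similarity was the Jaccard index of the sets of regions with a peak.

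The lists, the named loci and the tests were fixed before the data were examined. Named loci are members of a list past the threshold (up to 30 by adjusted p), the 10 (ends) or 5 (steps) largest changes in each direction past the threshold, and 18 regulators whatever their values; members of lists are also named as examples beside their list's count. The fit was tested on simulated data with 200 changed loci of at least 5 mean peaks. Of 2-fold changes 48, 44, 50, 43 and 46% were recovered for the 5 steps in order and 69% for the ends, and of 4-fold changes 89, 93, 95, 86, 86 and 95%. False loci were 17, 0, 0, 0.77, 3.65 and 3.53% of calls. The Fisher test was tried on 112973 simulated regions, 200 of them changed. It recovered 38% of regions set to a peak in 90% of libraries at one end and 5% at the other. For regions set to 70% in place of 90% it recovered 17%. So few changed regions cannot pass the adjustment over all regions. These shares therefore do not measure recovery at the adjusted threshold used for the region calls.

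Batch labels give a month for each library, so pairing comes from them and not from the replicate numbers, which match batches only in part. Deviations from stage means correlated by 0.10 on average in the 22 pairs of libraries from the same batch (-0.03 to 0.27) and by -0.02 in other pairs. The labels state a shared batch, so the batch was fitted as a block in an alternative. Its value stands beside the results that it changed, except at named loci where only the number of alternatives that lost the call is given. A Fisher test stratified by batch was void, since 1 batch held both ends, with 2 early libraries and 1 late one. Other alternatives were lists cut to the 32351 strongest peaks (lists of equal length), no scaling, scaling to the number of regions with a peak, a −log10 p of at least 5, windows of 501 bp around summits, a peak over 50% of a region, support in 3 libraries, a distance of 50000 bp, a pseudocount of 0.5, loci with at least 1 or 5 regions, limma without the trend and robust options, no chromosome X, and each library left out in turn. Leaving out ETP replicate 3 and DN4 replicate 1 together, scaling to regions with a peak and leaving out regions present in all 17 libraries from the share at gene ends were added after the data had been seen.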

Results

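Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts accessible DNA, in mouse thymocytes sorted at 6 consecutive stages before CD4 and CD8 appear. The series concerns T cell development from expanded progenitors, and the libraries used here are its in vivo reference stages. Early thymic progenitors (ETP) were sorted as Kit-positive cells without CD25, and the ETP_trans gate held cells with low CD25. DN2a and DN2b cells carried CD25 with high or intermediate Kit, DN3 cells had lost CD44 and Kit but kept CD25, and DN4 cells had lost CD25 as well. Each stage had 3 libraries, except DN4 with 2, and each library came from thymi pooled from 8 to 10 mice. The labels give 5 library batches. The authors' peak lists held 54577 ± 19303 peaks in ETP (SD, n = 3), 81800 ± 8307 in ETP_trans, 81938 ± 9018 in DN2a, 77870 ± 5608 in DN2b, 79362 ± 4354 in DN3 and 70214 ± 1731 in DN4 (SD, n = 2). The shortest list, of ETP replicate 3, had 32351 peaks and the longest, of DN2a replicate 3, had 91263. Read depth is unknown, so a region without a peak was one not listed by the peak caller, which does not show that it was closed.

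The peaks of all 17 lists merged into 112973 regions on the autosomes and chromosome X (mm10) that held a peak in at least 2 libraries, and 21420 of them held one in all 17. Each region was assigned to the nearest gene within 100000 bp, and the number of regions with a peak was compared at 11003 gene loci with at least 3 regions. Changes are differences between stages in log2(n + 1), where n is that number scaled to the median list length; this scale understates the change of a locus with few or no peaks on one side. Libraries of the same stage shared more regions (mean Jaccard index 0.70 over 16 pairs, SD 0.0869) than libraries of different stages from the same batch (0.627, SD 0.109, 22 pairs) or from different batches (0.568, SD 0.106, 98 pairs). The difference between same-stage and other pairs was 0.121 (permutation test of stage labels within batches, one-sided p = 2e-05 with 100000 resamples). The index declined from 0.667 for stages next to each other to 0.424 for ETP against DN4. Of 17 libraries 13 were most similar to a library of their own stage, and 11 in lists of equal length. ETP_trans replicate 2 and DN2a replicate 3, both May_2024, were most similar to each other. DN2b replicate 1 was most similar to DN3 replicate 2, both Nov_2023, and ETP_trans replicate 3 to DN2a replicate 3 of another batch.

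The ends of the series were compared first, with DN3 and DN4 as the late stages and ETP and ETP_trans as the early ones, to ask which loci opened and closed between uncommitted progenitors and cells around β-selection. Genes of the T cell program gained open regions together. Of 23 tested loci of T specification factors, 15 rose and 1 fell. The largest rise among them was at Bcl11b, the zinc finger factor that completes commitment to the T lineage (chr12:107910403-108004145). Its locus held a peak in 4 ± 1.73 of 47 regions in ETP, 10.3 ± 4.16 in ETP_trans, 16 ± 1.73 in DN2a, 23 ± 7.94 in DN2b, 35.7 ± 5.13 in DN3 and 31 in both DN4 libraries, a log2 rise of 2.10 (SE 0.17, limma adjusted p = 1.99e-07). Ikzf3, which encodes Aiolos, rose by 1.67 (SE 0.23), Tox by 1.10 (SE 0.12) and Ets1 by 1.02 (SE 0.11), from 12.7 ± 4.93 of 48 regions in ETP and 18 ± 4 in ETP_trans to 29.7 ± 3.06 in DN3 and 41 ± 1.41 in DN4. Lef1 rose by 0.89, Tcf12, which encodes the E protein HEB, by 0.77 and Myb by 0.75. In all 5 late libraries each of these loci lay above all 6 early libraries. Runx3 was the member that fell, by 0.30 (adjusted p = 0.000938). The list moved up as a set (camera adjusted p = 1.29e-06; adjusted p = 0.107 with an estimated correlation), and adjusted over the list alone 16 members rose and 2 fell.

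Components of the T cell receptor complex and its signalling rose most uniformly, at 16 of 17 tested loci with none lower. Themis, which tunes T cell receptor signals during selection, rose by 1.67 (SE 0.20, adjusted p = 7.42e-06), from 0.667 ± 0.577 of 13 regions in ETP and 3.67 ± 0.577 in ETP_trans to 8.33 ± 2.08 in DN3 and 7 ± 1.41 in DN4. The CD3 chain genes Cd3g and Cd3e rose by 1.30 and 1.18, the recombinase gene Rag1 by 0.94, the kinase gene Itk by 0.87 and the zeta chain gene Cd247 by 0.75, while the kinase gene Fyn was the locus that did not pass (0.03, adjusted p = 0.725). The set test gave an adjusted p of 1.86e-07 (adjusted p = 0.0506 with an estimated correlation), and adjusted over the list alone 16 members rose and 0 fell. Of 19 loci of β-selection and the later CD4 CD8 double-positive stage, 10 rose and 1, Nr4a1, fell by 0.39. The CD8 coreceptor genes led them: Cd8a rose by 2.35 (SE 0.23), from no peak in any ETP library and 0.667 ± 0.577 in ETP_trans to 4.67 ± 1.15 in DN3 and all 6 regions in both DN4 libraries, and Cd8b1 by 2.34 (SE 0.25). Aqp11 followed at 1.24 and Cd4 at 1.05. This list passed as a set (adjusted p = 0.00137; adjusted p = 0.219 with an estimated correlation), with the same 10 and 1 adjusted over the list alone. Among T cell receptor segments, 6 of 12 Tra loci rose and 1 fell, with Trav17 up by 1.59 (set adjusted p = 0.0227; adjusted p = 0.219 with an estimated correlation and 0.467 in lists of equal length). For Trd 4 of 6 loci rose, for Trb 3 of 7 and for Trg 2 of 6, and these sets did not pass (adjusted p = 0.0625, 0.210 and 0.0818). Adjusted over each list alone, the counts were 6 up and 1 down for Tra, 4 and 1 for Trd, 4 and 1 for Trb, and 2 and 0 for Trg.

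Progenitor and myeloid loci lost open regions over the same interval. Of 18 progenitor transcription factor loci 10 fell and 1, Gfi1b, rose by 0.63. Bcl11a, a factor of lymphoid progenitors, fell by 1.27 (SE 0.12, adjusted p = 3.58e-07), from 15 ± 4.58 of 33 regions in ETP and 24.3 ± 3.51 in ETP_trans to 10 in every DN3 library and 7 ± 1.41 in DN4. The stem cell factor genes Meis1 and Pbx1 fell by 1.04 and 0.71, Mycn fell by 0.97 and Hhex fell by 0.59. The set moved down (adjusted p = 0.00211; adjusted p = 0.164 with an estimated correlation), with 1 up and 10 down adjusted over the list alone. Of 17 myeloid and dendritic cell loci, 9 fell and 2 rose. Csf1r, the receptor for the macrophage growth factor, fell by 2.18 (SE 0.29). Cebpa, a master factor of myeloid cells, fell by 1.92 (SE 0.20), from 5.67 ± 2.08 of 8 regions in ETP, 7 ± 1 in ETP_trans and 7.33 ± 1.15 in DN2a to 2.67 ± 1.53 in DN2b and 1 in both DN4 libraries. Cd33 fell by 1.90, the myeloperoxidase gene Mpo fell by 1.82 and the dendritic cell genes Siglech and Itgax fell by 1.66 and 1.65, while Cd14 rose by 0.97 and Irf8 by 0.25. The set adjusted p was 0.00750 (adjusted p = 0.0705 with an estimated correlation), and adjusted over the list alone 3 rose and 9 fell. Among progenitor receptors Cd34 fell by 1.19 and Cd93 fell by 0.98, but Sell and Cxcr4 rose by 0.84 and 0.36. That set of 12, with 5 lower and 2 higher, did not pass (adjusted p = 0.251).

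Lists for other cell types that the gates could hold did not pass as sets. Natural killer and innate lymphoid loci had 4 lower and 1 higher of 15 (adjusted p = 0.247), B cell loci 1 lower and 1 higher of 13 (0.982), γδ T cell loci 3 lower and 3 higher of 12 (0.982; here the median was 0.01 and the mean -0.14), erythroid, megakaryocyte and mast cell loci 5 lower and 1 higher of 9 (0.0625; 0.0156 unscaled) and thymic stroma 5 lower of 11 (0.0507; 0.0491 unscaled). The 9 housekeeping loci had 1 lower and the 4 loci of the HoxA cluster 2 higher and 1 lower (0.982 and 0.653). Adjusted over each list alone, all 7 of these sets and the progenitor receptors kept those counts.

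Among all loci the largest rise was at Ptpn14, a phosphatase gene on chr1:189728216-189876695, at 2.71 (SE 0.21). It held 1 ± 1 of 25 regions with a peak in ETP, 4.67 ± 1.15 in ETP_trans and 14.3 ± 1.15 in DN2a. Gm46320 (2.61), Tenm1 (2.40) and Gm52008 (2.34) were among those that followed, and the gene models Gm46320 and Gm52008 lie on the same side of Bcl11b on chromosome 12, the farther one 1238315 bp from it. The largest fall was at Il1rl1, the IL-33 receptor gene, at -2.73 (SE 0.20, adjusted p = 4.45e-08), with 4 ± 2.65 of 10 regions in ETP, 7.67 ± 2.08 in ETP_trans, 1.33 ± 0.577 in DN2b and no peak in any DN3 or DN4 library. Ntm (-2.66), Fshr (-2.48), Sh2d1b1 (-2.35) and Tcerg1l (-2.33) followed. The 10 largest rises also held H2-Q2, F2 and Pgpep1l with Cd8a, Cd8b1 and Bcl11b, and the 10 largest falls Abca13, Clec5a, Gm9733 and Alox5 with Csf1r. Further list members by adjusted p were Ets2 (0.98), Trdv5 (1.45), Cd163l1 (0.83), Zbtb46 (-0.96), Kcnk1 (-2.03) and Gp9 (-1.69; -0.67 and adjusted p = 0.122 with peaks over 50% of a region). Several regulators of the early program changed less or did not pass. Tcf7, the Notch-induced factor TCF-1, held 12.3 ± 2.08 of its 20 regions in ETP and 18 ± 1.41 in DN4 (0.22, adjusted p = 0.109). The values were -0.37 (0.121) at Lmo2, -0.18 (0.118) at Mef2c, -0.19 (0.119) at Flt3 and -0.04 (0.735) at Erg. Gata3 rose by 0.54 (adjusted p = 0.00300), Il2ra, which encodes CD25, by 0.46 (0.0135) and Notch1 by 0.32 (0.0129). In that order, 5, 0 and 4 of the 5 late libraries lay above all early libraries. With batch as a block, however, the adjusted p was 0.302, 0.173 and 0.238. Il2ra also missed the threshold without DN4 replicate 1 (0.0616) and Notch1 without DN4 replicate 2 (0.0726). Spi1, the PU.1 gene, fell by 0.50 (0.0194; 0.0674 with the block, 0.0882 unscaled, 0.121 without DN4 replicate 1 and 0.0504 without DN3 replicate 3). Kit stood at -0.32 (0.0265; 0.370 with the block and 0.541 unscaled, where it was -0.14), with adjusted p of 0.0544 and 0.0630 without ETP_trans replicates 1 and 3, 0.0589 without DN3 replicate 1 and 0.141 without DN4 replicate 2. Ptcra and Lyl1 had too few regions to test: the 2 Ptcra regions had no peak in any early library and at least 1 in every library from DN2a on, and the 1 Lyl1 region had a peak in all 17.

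In total 3929 of 11003 loci changed between the ends, 1861 higher and 2068 lower late. Without scaling to list length the split was 2138 higher and 979 lower, with a median shift of all loci of 0.13. Only the batch labelled Aug_2024 held both ends. Of 3442 loci called without its 3 libraries, 91.3% moved the same way within it, and with batch as a block 458 loci rose and 800 fell.

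**Figure D1:**
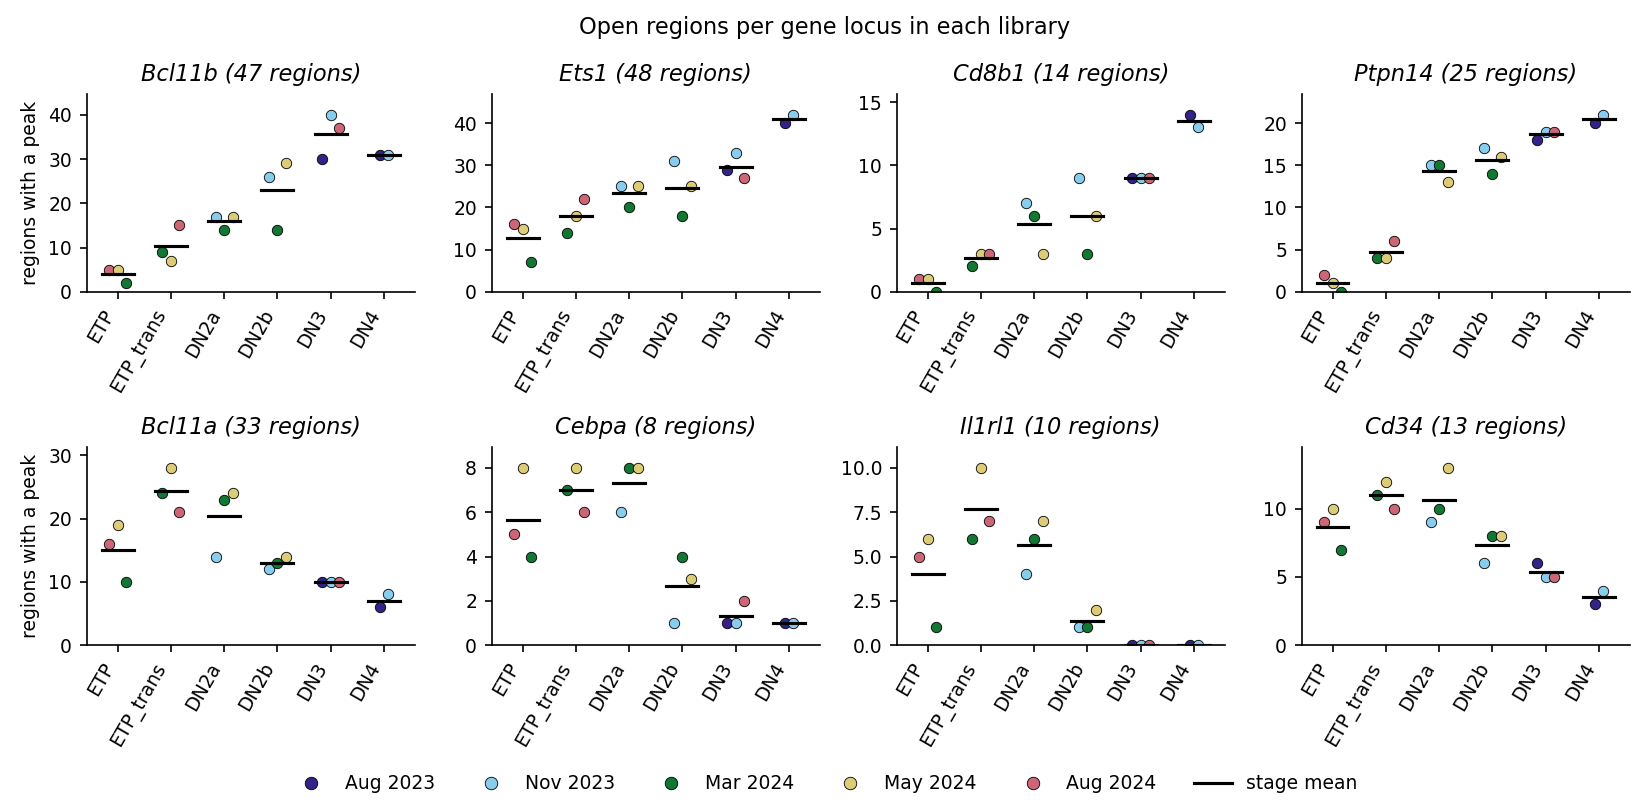
Number of regions with a peak (vertical axis) at 8 gene loci in each library, by stage (horizontal axis); points are libraries colored by batch and black bars are stage means. Bcl11b, Ets1, Cd8b1 and Ptpn14 gain regions across the stages, and Bcl11a, Cebpa, Il1rl1 and Cd34 lose them between DN2a and DN4.

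Single regions were tested between the same ends to locate the changes within loci. At Bcl11b, 10 regions had a peak in all 5 late libraries and in none of the 6 early ones, 7 of them within the gene and 3 outside it, the farthest 97218 bp away (chr12:107812438-107813185). The 1 region 44441 bp beyond the other end of the gene (chr12:108048586-108049121) had the opposite pattern. Ptpn14 had 7 such late regions, Cd8b1 6 and Ets1 5. At Gata3, 2 late regions lay 32581 and 28763 bp from the gene and 1 early region 53993 bp from it. Early regions included 1 within Spi1 (chr2:91086155-91086828), 1 at an end of Mpo (chr11:87793283-87794178), 2 near Cebpa, 3 beyond Bcl11a and 2 at Cd34. The 1 called region at Kit (chr5:75597712-75598657), within the gene, was late. Over whole lists, late and early regions numbered 55 and 4 for T specification factors, 25 and 3 for T cell receptor signalling and 25 and 2 for β-selection genes, but 8 and 10 for progenitor transcription factors, 6 and 4 for progenitor receptors and 10 and 9 for myeloid and dendritic cell genes. Of all assigned regions 3.25% were late and 1.66% early, and of the myeloid ones 4.65% and 4.19%. Two-sided Fisher exact tests called 5682 of 112973 regions (5.03%), 3695 late and 1987 early, all of them at the smallest p the design allows (p = 0.00216, adjusted p = 0.0430), and 15340 regions had an unadjusted p under 0.05. The test takes libraries as independent, but libraries within an end shared batches and only Aug_2024 held both ends. It therefore cannot part stage from batch. The balance turned to 2328 late and 3138 early in lists of equal length. Leaving out any 1 of the 11 libraries raised the smallest possible p to 0.00476 or 0.00794 and left 0 calls. Without ETP replicate 3 the regions present in all of one end and none of the other were 3695 late and 5448 early.

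**Figure D2:**
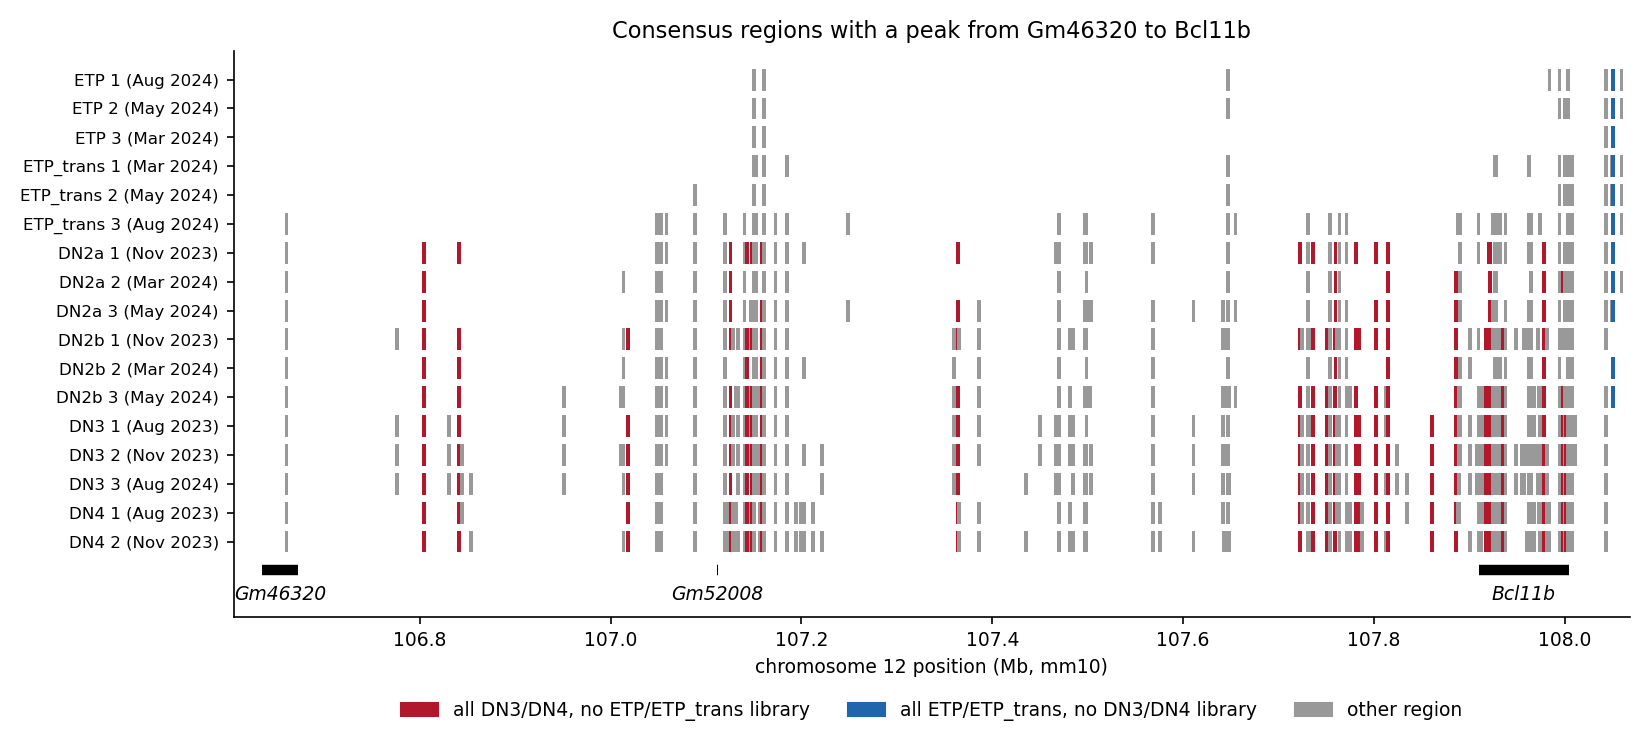
Map of chr12:106658227-108058247 (mm10; horizontal axis, position in Mb) with 130 consensus regions; each line is a library, and a mark is a region with a peak, drawn at least 4 kb wide. Red marks are the 27 regions present in all DN3 and DN4 and in no ETP or ETP_trans library, the blue mark is the 1 region with the opposite pattern, and gene bodies of Gm46320, Gm52008 and Bcl11b are drawn below.

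Late and early regions were chosen as present throughout one end and absent from the other, so the DN2 stages could only lie between. Within these limits DN2a was on average nearer the early and DN2b nearer the late stages, for gain and for loss. Early regions also needed a peak in the short list of ETP replicate 3 (1987 regions, against 5448 without that library). The shares of late and of early regions are therefore not selected alike and cannot be compared with each other. Of the regions open late, 41.7 ± 11.7% had a peak in DN2a and 72.1 ± 27.9% in DN2b (SD, n = 3 each; exact permutation test, two-sided p = 0.2). Of the regions open early, 94.1 ± 7.80% still had a peak in DN2a and 39.0 ± 22.2% in DN2b, with no overlap between the stages (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give). Within batches DN2b exceeded DN2a for late regions in all 3 shared batches, Nov_2023 (95.1% against 55.1%), Mar_2024 (41.1% against 33.9%) and May_2024 (80.2% against 36.1%). For early regions DN2b lay below DN2a in the same batches (15.5% against 85.2%, 59.5% against 98.2% and 41.9% against 99.1%). Called regions were less often at gene ends than uncalled ones. Within 1000 bp of either end of a gene lay 6.66% of late, 5.18% of early and 16.5% of uncalled regions (odds ratio 0.331, Fisher exact test, two-sided p = 2.09e-118, in which regions are not independent). The uncalled regions include the 21420 present in all 17 libraries, which cannot be called and lay there in 44.9%. Without them the uncalled share was 9.43% (odds ratio 0.629, Fisher exact test, two-sided p = 2.51e-18). Regions with a peak in nearly all libraries cannot be called either and stay in that share, so the calling may still set part of the contrast.

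**Figure D3:**
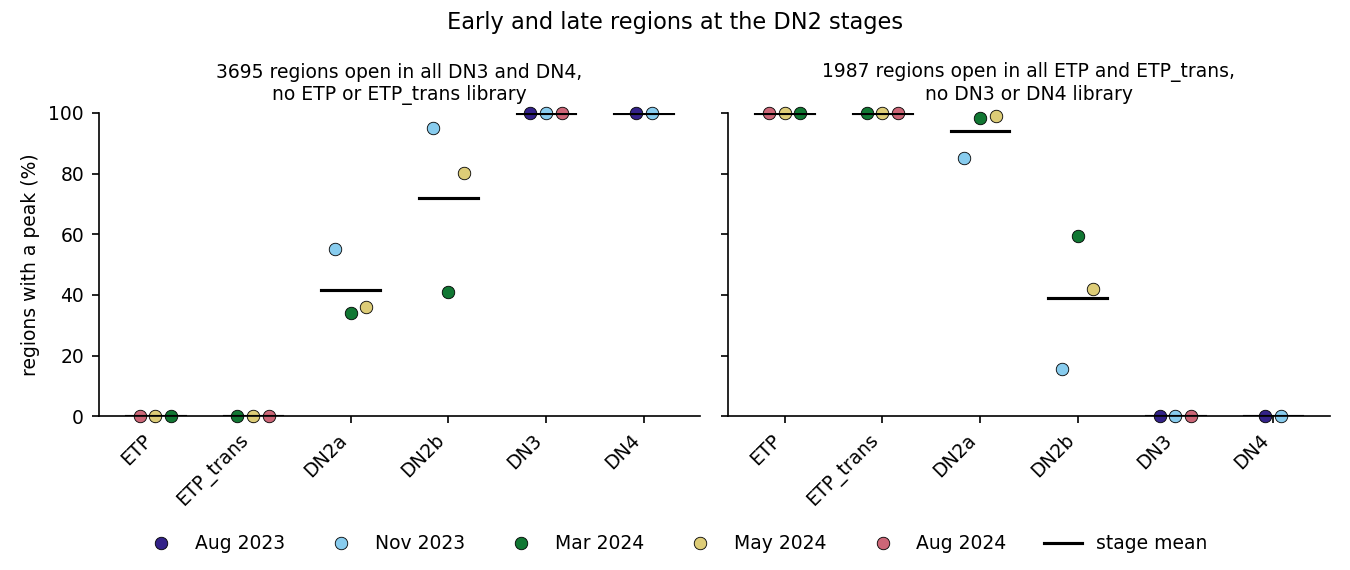
Percent of the 3695 late regions (left) and of the 1987 early regions (right) with a peak in each library (vertical axis), by stage (horizontal axis); points are libraries colored by batch and black bars are stage means. By definition ETP, ETP_trans, DN3 and DN4 lie at 0 or 100%, and the early regions lie at 85.2% to 99.1% in DN2a and 15.5% to 59.5% in DN2b.

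From ETP to ETP_trans, the step at which CD25 first appears, loci gained regions. Hhipl2 rose by 1.87 (SE 0.19, adjusted p = 9.60e-05), from no peak in ETP to 3 ± 1 of 6 regions, Gm41607 rose by 1.78 (SE 0.21) and Elp3, a tRNA-modifying enzyme gene, by 1.77 (SE 0.20), both from no peak in ETP. Elp3 missed the threshold in lists of equal length (0.33, adjusted p = 0.939), at a −log10 p of at least 5 (0.53, 0.458) and in summit windows (0.81, 0.0714). Gm41607 missed it at that −log10 p (0.27, 0.697) and with peaks over 50% of a region (0.83, 0.177), as did Hhipl2 with the latter (0.60, 0.170). Hephl1 rose by 1.74 (adjusted p = 0.0252; lost in 5 of 20 alternatives). Kdm5b, a histone demethylase gene, rose by 1.72 (SE 0.31; adjusted p = 0.0624 without ETP_trans replicate 2), and it, Hhipl2 and Gm41607 could not be tested in lists of equal length. Among members of the lists, Themis rose by 1.39 (SE 0.27, adjusted p = 0.0221), but it missed the threshold without ETP_trans replicate 1 (0.0796) or 3 (0.0904) and in lists of equal length (0.852). Sell, the homing receptor L-selectin, rose by 0.75 (adjusted p = 0.0329), a call lost without ETP replicate 3 (0.105), ETP_trans replicate 1 (0.138) or 2 (0.129), with batch as a block (0.0579) and in lists of equal length (0.959). The segment Trbv19 rose by 1.26 (adjusted p = 0.0318), lost in 7 of 19 alternatives. Bcl11b stood at 0.67 (adjusted p = 0.171). Trd segments moved up as a set (adjusted p = 0.0334; adjusted p = 0.406 with an estimated correlation, 0.654 in lists of equal length and 0.358 unscaled), with 0 of 6 loci past the threshold over all loci and 3 higher adjusted over the list alone. In total 113 loci rose and 1, Ctse, fell, by 0.73, but its difference was 0.14 in lists of equal length and 0.26 where peaks had to cover 50% of a region. In lists of equal length 5 loci rose, and unscaled 1933 rose and 0 fell with a median shift of all loci of 0.49. The count without 1 library was 510 (ETP replicate 2), 244 (ETP replicate 1), 82 (ETP replicate 3), 41 (ETP_trans replicate 1), 29 (ETP_trans replicate 2) and 26 (ETP_trans replicate 3). In simulated data for this step 17% of calls were false. The simulated changes were set only at loci of at least 5 mean peaks, so that share need not hold for loci with fewer. At single regions 3829 were gained (no ETP library, all ETP_trans libraries) and 1 lost, against 412 and 150 in lists of equal length.

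From ETP_trans to DN2a, some of the T cell lists moved up as sets at the preset correlation, but none of them with an estimated correlation, and 1 single locus passed. T specification factors moved up as a set (median log2 change 0.12, adjusted p = 0.000127; adjusted p = 0.246 with an estimated correlation), as did T cell receptor signalling (0.20, adjusted p = 0.00332; adjusted p = 0.246 with an estimated correlation), β-selection genes (0.21, adjusted p = 0.00173; adjusted p = 0.328 with an estimated correlation and 0.0673 with batch as a block) and Tra segments (0.26, adjusted p = 0.0185; adjusted p = 0.328 with an estimated correlation). No member passed over all loci, and adjusted over each list alone 0, 1, 1 and 0 rose. The β-selection and Tra sets missed the threshold in lists of equal length (0.103 and 0.0972). Cd3e stood at 0.88 (adjusted p = 0.598). The 1 locus past the threshold was Tmem270, at 1.09 (SE 0.17, adjusted p = 0.0319), from 1.67 ± 0.577 to 4.67 ± 0.577 of 6 regions. That call was lost with batch as a block (0.266) and without DN2a replicate 1 (0.175), 2 (0.138) or 3 (0.104) or ETP_trans replicate 1 (0.233) or 2 (0.106), although the rise stayed at 0.95 to 1.15 in these fits, and at a −log10 p of at least 5 the rise was 0.35. In all, 6 loci passed without ETP_trans replicate 3. By limma 529 loci had an unadjusted p under 0.05. At single regions 1019 were gained and 419 lost. A grouping of the same 6 libraries that kept each batch together gave 1579 such regions, more than the 1438 of the stages. That grouping also set the shorter lists against the longer ones. In lists of equal length the stages gave 722 and no other grouping more than 611.

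From DN2a to DN2b, the step at which T lineage commitment is placed, myeloid and dendritic cell loci moved down as a set (median -0.24, adjusted p = 0.000339; adjusted p = 0.0160 with an estimated correlation), with 0 of 17 past the threshold over all loci and 5 lower adjusted over the list alone. T cell receptor signalling genes moved up (median 0.18, adjusted p = 0.000878; adjusted p = 0.219 with an estimated correlation), as did T specification factors (0.12, adjusted p = 0.0443; adjusted p = 0.420 with an estimated correlation and 0.182 unscaled) and Trg segments (0.56, adjusted p = 0.0443; adjusted p = 0.237 with an estimated correlation and 0.0701 with batch as a block). Adjusted over each list alone these 3 sets had 0, 0 and 1 members up. The myeloid set (0.0864) and the T specification set (0.542) missed the threshold in lists of equal length. Of 16 changed loci 14 fell. Calml3 fell by 1.59 (SE 0.22, adjusted p = 0.00509) and C9orf72 fell by 1.39 (SE 0.20), and both missed the threshold without DN2a replicate 2 (0.0704). Nrg1, the growth factor neuregulin 1, fell by 1.56 (SE 0.24, adjusted p = 0.0126), which was lost without DN2a replicate 2 (0.108) or 3 (0.0818) or DN2b replicate 1 (0.0970). Il1rl1 fell by 1.44 (SE 0.27, adjusted p = 0.0334), with adjusted p of 0.185 and 0.214 without DN2a replicates 2 and 3 and 0.177, 0.0688 and 0.0610 without DN2b replicates 1, 2 and 3. The falls shrank, in lists of equal length, to -0.53 for Calml3 (adjusted p = 0.470), 0.00 for C9orf72 (1.0), -0.67 for Nrg1 (0.227) and -0.53 for Il1rl1 (0.468). Unscaled, the 4 missed the threshold with falls as large as reported (-1.67, -1.46, -1.64 and -1.51), and with peaks over 50% of a region they missed it at -1.56, -1.23, -2.23 and -2.01. Gm5861 fell by 1.57, and the loci that rose were Nr2c2 (0.97) and Padi3 (0.88), calls lost in 11 of 20, 11 of 20 and 12 of 21 alternatives. Lists of equal length gave 81 higher and 138 lower loci, of which 1 was among the 16. The count was 0, 3, 3, 4 and 29 without DN2a replicate 2, DN2a replicate 3, DN2b replicate 1, DN2b replicate 3 and DN2b replicate 2. At single regions 659 were gained and 2365 lost (633 and 983 in lists of equal length).

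From DN2b to DN3, where rearrangement of Tcrb takes place, Lrrc52 fell by 2.07 (SE 0.29, adjusted p = 0.00808), from 3.33 ± 0.577 of 6 regions to none, and Abca13, a lipid transporter gene, fell by 1.74 (SE 0.29, adjusted p = 0.0435), from 2.67 ± 1.53 of 7 to none. Lrrc52 missed the threshold without DN2b replicate 2 (0.150) or DN3 replicate 2 (0.0558). Abca13 missed it without DN2b replicate 2 (0.413) or 3 (0.341) or DN3 replicate 1 (0.0806), 2 (0.158) or 3 (0.126). With batch as a block the adjusted p was 0.230 and 0.629. The folds shrank to -0.33 (adjusted p = 0.667) and -0.67 (0.336) in lists of equal length and to -0.36 and -0.65 (both 0.986) at a −log10 p of at least 5, and with peaks over 50% of a region the adjusted p was 1.0 and 0.808. T specification factors moved up as a set (median 0.13, adjusted p = 0.0248; adjusted p = 0.501 with an estimated correlation, 0.379 with batch as a block and 0.0617 unscaled), and erythroid, megakaryocyte and mast cell loci moved down (median -0.43, adjusted p = 0.0248; adjusted p = 0.305 with an estimated correlation and 0.379 with batch as a block). Both missed the threshold in lists of equal length (0.413 and 0.296), and adjusted over each list alone 0 members of either passed. These 2 loci were the only ones past the threshold, with 733 at an unadjusted p under 0.05 in limma and 0 past it with the block. Without DN2b replicate 1 the count was 27, without DN2b replicate 3 it was 1, and without DN2b replicate 2 or DN3 replicate 2 it was 0. At single regions 900 were gained and 871 lost.

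From DN3 to DN4, the passage through β-selection, more loci lost than gained regions. Fhod3, a formin gene, fell by 2.16 (SE 0.35, adjusted p = 0.00343), from 7.33 ± 1.15 of 22 regions to 1 ± 1.41. Nrxn1 fell by 2.15 (SE 0.36), Tril fell by 2.04 (SE 0.41; adjusted p = 0.0649 and 0.0722 without DN4 replicates 1 and 2), Rgs20 fell by 1.94 (SE 0.34) and Trim30c fell by 1.94 (SE 0.30), the last 2 from 3 regions in each DN3 library to none in DN4. Gp9, a platelet glycoprotein gene, fell by 1.62 (SE 0.30, adjusted p = 0.00524), from 2.33 ± 1.15 of 4 regions to none, and Ifng fell by 0.64 (SE 0.13, adjusted p = 0.00967; 0.154 without DN4 replicate 2). Of these, only Fhod3 also passed in lists of equal length, where Nrxn1 (-0.33, 0.844), Gp9 (0.00, 1.0) and Ifng (-0.41, 0.146) did not and Rgs20, Trim30c and Tril could not be tested. With peaks over 50% of a region each but Fhod3 missed the threshold (0.261 for Rgs20 and 0.140 for Trim30c), as did Trim30c at a −log10 p of at least 5 (-0.80, 0.621). Ets1 rose by 0.63 (SE 0.17, adjusted p = 0.0463), from 29.7 ± 3.06 to 41 ± 1.41 of 48 regions. That call was lost without any 1 of the 5 libraries (0.0979, 0.0705 and 0.174 without DN3 replicates 1, 2 and 3, and 0.141 and 0.284 without DN4 replicates 1 and 2) and in lists of equal length (0.218). Other list members past the threshold were Cd33 (-1.14), Trbv26 (-1.90) and Mitf (-0.62), lost in 6 of 21, 8 of 20 and 14 of 21 alternatives, and in lists of equal length Cd33 and Trbv26 did not change at all. The largest rises were at Tlr1 (1.30), Cxxc4 (1.11), Zfp180 (1.11), Nox1 (1.05) and Cx3cr1 (0.94), lost in 6 of 21, 7 of 17, 12 of 17, 12 of 17 and 13 of 21. β-selection genes moved up as a set (median 0.23, adjusted p = 0.00996; adjusted p = 0.580 with an estimated correlation), with 0 of 19 past the threshold over all loci and 3 higher adjusted over the list alone. T specification factors did too (0.10, adjusted p = 0.0436; adjusted p = 0.580 with an estimated correlation and 0.340 unscaled), with 2 higher adjusted over the list alone. In total 19 loci rose and 275 fell. Lists of equal length gave 88 and 300, with 46 loci in common with the 294, all lower, and unscaled lists 0 and 156 with a median shift of -0.17. The count was 165, 140 and 186 without DN3 replicates 1, 2 and 3, and 160 and 118 without DN4 replicates 1 and 2. At single regions 2192 were gained and 6291 lost, against 1805 and 2193 in lists of equal length.

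**Figure D4:**
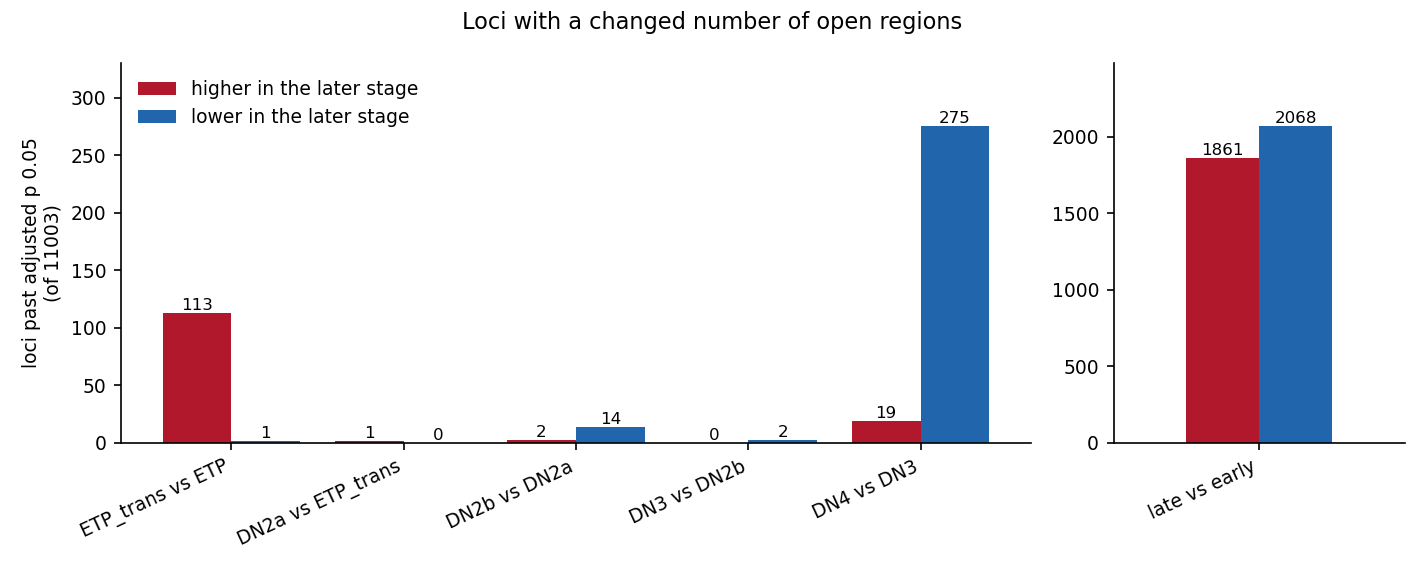
Number of loci past an adjusted p of 0.05 among 11003 tested (vertical axes), higher (red) or lower (blue) in the later stage, for 5 consecutive steps (left) and for the 2 ends of the series (right, on its own scale). Gains prevail from ETP to ETP_trans (113 against 1) and losses from DN3 to DN4 (19 against 275), both with lists of unequal length.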

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

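All tests in this part that weigh an explanation, and those on other groupings of the libraries, were chosen after the results had been seen.

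From ETP to ETP_trans, 3829 regions were gained and 1 lost, and 113 loci rose and 1 fell. In lists of equal length the number of all-or-none regions was 14.7% of that in full lists, against 47.1% to 53.4% at the other 4 steps. Most of the excess of gains may therefore go with the shorter ETP lists. The cut removes such an excess whether those lists are short from depth or from fewer open regions, so it cannot tell these apart. The short list of ETP replicate 3 alone is argued against, since without that library 97.6% of all-or-none regions were still gains. A larger set of open regions in ETP_trans, the biological alternative the design names, stays open, since lists cut to equal length cannot show a larger set. In lists of equal length 73.3% were gains, but another grouping of the 6 libraries gave 528 all-or-none regions against 562 for the stages.

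From DN3 to DN4, losses outnumbered gains for regions (6291 against 2192) and for loci (275 against 19). For regions, 54.9% of all-or-none regions were losses in lists of equal length. Such lists pull gains and losses towards balance whether the DN4 lists are short from depth or from a real loss. This value therefore cannot tell list length from a real loss. A loss also needs a peak in 3 libraries and none in 2, and a gain the reverse, so the counts are not taken alike. For loci, losses still prevailed in lists of equal length (77.3% of changed loci, and 75.5% or more without any 1 library), which argues against list length as the whole cause of such an excess, but on largely other loci. Of the 275 loci called lower, 192 could be tested in lists of equal length, and 137 kept their direction. Only 46 (24.0%) were called lower again, and the median fell from -0.97 (interquartile range 0.43) to -0.40 (0.86). For the called losses themselves list length therefore cannot be told apart from a real loss, since shorter lists also leave fewer regions to test. The wide peaks of DN4 replicate 1 are argued against too, since without that library 96.9% of changed loci were lower. A loss of accessible regions at β-selection stays open and was not tested against other differences between the gates.

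The DN2b libraries differed in how far they had gained late regions and lost early ones. DN2b replicate 1 (Nov_2023) had 95.1% of late and 15.5% of early regions, and DN2b replicate 2 (Mar_2024) 41.1% and 59.5%. List length is argued against, since the library with more late regions had fewer early ones, a difference of -44.0 percentage points against a range of 13.9 in DN2a. A batch effect, such as a gate set differently on each day, cannot be told apart from a difference between the pools. The 3 batches had the same order in DN2a and DN2b for late regions, and the chance of that with 3 batches is 0.167. For early regions Nov_2023 was lowest in both stages (85.2% and 15.5%). Only Mar_2024 and May_2024 changed order, at 98.2% and 99.1% in DN2a and at 59.5% and 41.9% in DN2b. At the ends that defined these regions, Nov_2023 libraries were all late and Mar_2024 and May_2024 libraries all early. The choice of regions may therefore carry batch into these shares, and the order does not speak against it.

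The number of changed loci was set beside other groupings of the libraries into sets of the same sizes. For the ends of the series 1 of 100 groupings, the real grouping, gave as many loci (3929, against at most 2317 in the others). Chance is argued against there, but the groupings were drawn across batches and cannot part stage from batch. All early libraries came from the Mar_2024, May_2024 and Aug_2024 batches, and of the late libraries only DN3 replicate 3 (Aug_2024) did. With batch as a block fewer loci changed. As many regions were called in 1 of 100 (5682 against 0), but that count drops to 0 whenever too few regions reach the smallest p. Counted at that p with no adjustment, the highest other grouping gave 3461 regions, with ETP replicate 3 set among the late libraries. For ETP_trans against ETP the stages gave 114 loci and the highest other grouping 4, for DN2a against ETP_trans 1 and 0, for DN2b against DN2a 16 and 1, and for DN3 against DN2b 2 and 1. Each was 1 of only 10 groupings, too few for a share under 0.05. For all-or-none regions between ETP_trans and DN2a, a grouping that put the Mar_2024 and Nov_2023 libraries against the May_2024 and Aug_2024 ones gave 1579, above the 1438 of the stages. That grouping also set the shorter lists against the longer ones, and in lists of equal length the stages gave 722 and other groupings at most 611. In the 4 libraries of the 2 shared batches the stages parted 6295 regions, the batches 5900 and the third grouping 1699. Of the 5900 regions, 5386 had a peak only in the May_2024 libraries, whose lists are longer, and 514 only in the Mar_2024 ones. Batch and list length therefore cannot be told apart in these counts. From DN3 to DN4 the stages parted 10997, the batches 2757 and the third grouping 2035.

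Signal outside the measured regions was seen in every list. Peaks on unplaced contigs numbered 26 to 69 per library. Regions with a peak in a single library, left out of the tests, numbered 33038. DN4 replicate 1 held 6668 of these, ETP_trans replicate 3 held 4536, DN3 replicate 3 held 3809, ETP replicate 1 held 3516 and ETP replicate 3 held 1. No stage had 4 libraries, and a library far from the rest of its stage was not tested for. ETP replicate 3 had a Jaccard index of 0.499 with its most similar library, against 0.6955 or more for every other library.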

How the results depend on the processing

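Leaving out ETP replicate 3 with DN4 replicate 1, scaling to regions with a peak and, for the share at gene ends, leaving out regions present in all 17 libraries (odds ratio 0.629 in place of 0.331) were tested after the data had been seen. Of 241 alternative values for summary results, 120 kept the reported value, which for counts means a total within 1.5 times. The balance of higher and lower was not part of that rule. Fisher calls in lists of equal length are thus among the 120 although their balance turned. Of 89 locus results past the threshold, 1875 of 2150 alternative values kept direction and side, 273 lost the threshold and 2 reversed, both for Ctse (0.14 in lists of equal length, 0.26 with peaks over 50% of a region). At the ends 36 of 54 named loci were tested and passed in all 27 alternatives, and 12 more passed in each alternative that could test them. Most of the 54 were named for a small adjusted p or a large change in these data. Their share therefore does not carry over to all changed loci. Of the 275 values that lost the threshold or reversed, 220 kept a change no more than 1.5 times below the reported one, so most were lost by p. None of the 18 in lists of equal length did, and 5 of 24 at a −log10 p of at least 5. By setting, results lost or reversed were 34 of 89 with peaks over 50% of a region, 24 of 71 at a −log10 p of at least 5, 18 of 63 in lists of equal length and 20 of 89 unscaled. Read depth is unknown, and where no value shows it, the cause was not tested.

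Numbers of changed loci are given in the order ETP_trans against ETP, DN2a against ETP_trans, DN2b against DN2a, DN3 against DN2b, DN4 against DN3 and ends, leaving out those within 1.5 times. In lists of equal length they were 5, 25, 219 and 41 for the first 4. At a −log10 p of at least 5 they were 181, 0, 1, 5, 164 and 2576. With peaks over 50% of a region they were 1538 for the first step, 0 for the next 3 and 7 for the last. Unscaled they were 1933 for the first step, 0 for DN2b and 156 for DN4. Summit windows gave 3, 9 and 1 for DN2a, DN2b and DN3, loci with at least 5 regions 0, 8 and 1, and loci with at least 1 region 208, 15, 28 and 8 for the first 4 steps. Plain limma gave 3 for DN2a and 7 for DN3, and scaling to regions with a peak 1 for DN3. Without ETP replicate 3 and DN4 replicate 1 the numbers were 4 for DN2a, 65 for DN2b and 458 for DN4, and all-or-none regions of DN4 against DN3 were 13803.

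With the batch as a block, which takes its pairing from the labels, 0 loci changed in DN2a against ETP_trans, 0 in DN3 against DN2b and 1258 at the ends, of which 1213 were among the 3929, and 0 lists passed for DN3 against DN2b. Within shared batches all-or-none regions were 6295 for DN2a against ETP_trans and 16304 for DN3 against DN2b, where 1 batch was shared; fewer libraries relax the criterion. Beside these, the block changed the calls printed with it and no other call of a list or count of loci by over 1.5 times. It cost 16 of 89 named locus results the threshold, some of them given above without its value. With the replicate number as a block, which does not pair the libraries (mean correlation of deviations 0.01), 0 loci changed in DN2a against ETP_trans and 5 in DN2b against DN2a. No block could be used in the Fisher test.

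With an estimated correlation 0 lists passed in each comparison except DN2b against DN2a, with 1. In lists of equal length 0, 1 and 0 lists passed for ETP_trans, DN2b and DN3. Fisher calls were 3323 at the stricter −log10 p and 0 with peaks over 50% of a region. All-or-none regions for the 5 steps were 2160, 726, 1643, 978 and 5078 at the stricter −log10 p and 562, 722, 1616, 904 and 3998 in lists of equal length.

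Without 1 library in turn, changed loci ranged over 26 to 510, 0 to 6, 0 to 29, 0 to 27 and 118 to 186 for the steps and 3060 to 4635 for the ends, and Fisher calls were 0 throughout because fewer libraries raise the smallest p. All-or-none regions ranged over 3956 to 8216, 2611 to 4087, 4008 to 7832, 2690 to 5654 and 10727 to 14805, as fewer libraries relax the criterion. Where 1 library was left in DN4, it was assumed to vary like the other stages. Motif tests were not run for want of a genome.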

Other observations

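The genes in the next 2 paragraphs were chosen after their values were seen, and the stretch beside Bcl11b was chosen because late regions were dense in it.

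Regions with a peak in every library of 1 stage and in no other library numbered 1110 in DN4, 339 in DN3, 145 in ETP_trans, 17 in DN2a, 12 in DN2b and 1 in ETP. DN4 had 2 libraries and the other stages 3, so its count cannot be ranked with theirs. The median was 43 in other pairs of libraries and 3 in other sets of 3. The count of ETP is limited by the short list of its replicate 3. The DN4 regions were most frequent at Ikzf3, which encodes Aiolos (7 regions), and the gene model Gm52008 (5). Genes with 4 included Foxp1, a forkhead factor of quiescent lymphocytes, Glb1 and the Wnt pathway factor gene Lef1. The DN3 regions were most frequent at Bcas3 (3), and genes with 2 included 6030468B19Rik, Add3, Cux2 and Dop1b. No other pair of libraries had more than 671 such regions and no other set of 3 more than 293. For ETP_trans, DN2a, DN2b and ETP, 7, 97, 139 and 502 of the 675 other sets of 3 libraries had as many as the stage. Among all genes, Nck2, an adaptor of T cell receptor signalling, had the most late regions (13 of 59), ahead of Bcl11b (10) and Itpr2 (8). Genes with 7 included Hdac4, Msi2 and Ptpn14. The most early regions lay at Inpp5a (6 of 22), a phosphatase gene, then at Agap1, Parvb and Prkcb (4 each).

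Late regions were dense in the stretch between Gm46320 and Bcl11b (chr12:106672088-107910402, 1238315 bp), where regions assigned to Bcl11b and Gm52008 lie. Of its 93 regions 20 were late (21.5%, against 3.27% of all regions) and 0 early. The number of its regions with a peak was 2.67 ± 0.577 in ETP (mean ± SD, n = 3), 11.7 ± 12.4 in ETP_trans, 33.3 ± 8.08 in DN2a, 49 ± 14.8 in DN2b, 66.7 ± 4.51 in DN3 and 65.5 ± 3.54 in DN4 (n = 2). The choice of the stretch sets early and late libraries apart, so their difference is no finding of its own. ETP_trans replicate 3 had 26 regions where the other ETP_trans libraries had 5 and 4.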
